A study of Mus musculus with 6 samples.

How the data were processed

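Total RNA was sequenced from crypts of the mouse ileum, the distal small intestine, in 6 libraries. Per the labels, 3 libraries came from mice with floxed Adar alleles only (Adar fl/fl, the control group). The other 3 libraries came from mice that carried the same alleles and the Villin-CreERT2 transgene (Adar iΔgut). CreERT2 is a Cre recombinase that becomes active when tamoxifen binds it, and the villin promoter directs it to the intestinal epithelium. Both genotypes received tamoxifen, and the time given is day 3. Per the labels' protocols, the tissue was not cultured, RNA was extracted with a column kit (RNeasy Mini) and libraries were made after Illumina's instructions. The labels number the libraries of each genotype as biological replicates. Read strandedness is not given in the sources used here.

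The measurements came from a single table of the authors' own comparison. Per the submitters' processing notes, STAR, Cufflinks and the mouse genome build GRCm38 were used, without versions or parameters. Per the file headers, the authors gave each gene 1 FPKM value (fragments per unit of transcript length, scaled to the number of fragments) in a condition named con and 1 in a condition named TMX. Also per the file headers, the authors' table holds a test statistic, which is a score, with its p-value, a q-value, a status and a call. Its layout is that of the differential test in the Cufflinks package, although no header names the program. The deposited log2 fold change equalled the log2 of the TMX value plus 1 over the con value plus 1, and the deposited signed score equalled the negative log10 of the p-value with the sign of that fold change. The deposited q-value equalled the Benjamini-Hochberg value over the 15762 genes with status OK, and the authors called a gene at a q under 0.05. The lowest p-value that the deposited table holds is 5e-05, shared by 704 genes, which all have the q-value 0.00112.

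The pooling of libraries into conditions was done by the authors, and no value per library was used here. Replicate numbers, spread between libraries and sequencing depth therefore could not be read from the values, and no standard deviation or interval is given for an expression value. That all 3 libraries of each genotype entered the authors' test is not stated in the sources used here. The table does not give genotypes for its conditions. The condition con was read as Adar fl/fl and TMX as Adar iΔgut by elimination, since both genotypes received tamoxifen. Adar itself had a higher value in TMX, against that reading, so directions are given for the condition labelled TMX.

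The table lists 55446 genes. Of these, 15762 were tested by the authors, 39624 had too little signal for a test by their status, and 60 had a status for excess data. Of those 60 genes, 57 were listed at 0 in TMX and 35 at 0 in con, so their values were left out, except from the summed FPKM of each condition. All 55446 gene identifiers, versions included, were found in the GENCODE vM21 annotation of GRCm38. A spreadsheet had turned 27 gene symbols into dates, and these were restored through the identifiers. The locus in the table equalled the annotated gene for 62.7% of the genes. For the other 20686 genes it covered more than the gene, as where overlapping genes were merged, so FPKM of overlapping genes is less certain. How reads shared by near-identical paralogs were divided is not given in the sources used here. Coordinates are 1-based and come from the annotation.

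The design written before the data were examined planned a test over the 6 libraries, and for a file with no value per library it planned a description of the authors' table with no new test. The second course was taken. Before the data were examined, 29 gene lists with 605 entries were also written from textbook knowledge of the tissue. For each list the authors' calls were counted in each direction, over all genes tested and after Benjamini-Hochberg adjustment of the authors' p-values over the list alone. The median log2 fold change of each list with at least 3 tested members was set against 10000 random lists of the same size, matched on mean FPKM in 20 bins of the tested genes. A list was said to stand apart when its median lay below the 2.5th or above the 97.5th percentile. This describes the values of these pooled conditions and is not a test across mice. On simulated data made by reassigning the log2 fold changes of the 15762 tested genes at random, 8 of 100 lists of 20 genes stood apart, and 100 of 100 did after a shift of 1 on the log2 scale. The simulation drew fewer random lists than 10000 for each list. Reassignment also removes the link of fold change with expression level and between members of a list. How often lists of genes that vary together stand apart is therefore not shown. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

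The rule for named genes was also written before the data were examined. It takes Adar, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change at a mean FPKM of at least 1, and up to 4 tested members of each list with the lowest p-value, as well as members that go against a list. Predicted gene models, pseudogenes and immunoglobulin or T cell receptor segments were left out of the largest changes. Members with equal p-values were taken in alphabetical order. Of the genes that the rule takes, 1 is not reported here. The part of the rule that asks for no overlap between libraries could not be applied to pooled values. Other genes, among them Isg15, Mx1, Rsad2, Ripk3, Ly6a, Lyz2 and Vim, and the gene families of the closing section, were chosen after their values were seen. Alternatives were another threshold, a fold minimum, no filter on low values, another pseudocount and a median-of-ratios rescaling. A filter on mean FPKM, protein-coding genes alone and centring on highly expressed genes were added after the data were seen.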

Results

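The series addressed what loss of ADAR, an enzyme that converts adenosine to inosine in double-stranded RNA, does to the intestinal epithelium, in work on an ADAR variant and bowel inflammation. RNA was sequenced from ileal crypts of 3 Adar fl/fl and 3 Adar iΔgut mice given tamoxifen, at day 3. The authors' deposited table held 1 pooled FPKM for the condition con and 1 for the condition TMX for each of 55446 genes. These values summed to 632180 FPKM in con and 539762 FPKM in TMX. The sums include the 60 genes with a status for excess data, of which 57 were listed at 0 in TMX and 35 in con. The difference between the sums may therefore partly reflect that status. The depth of each library is unknown, and no replicate error stands beside an FPKM value. Differences were therefore judged by the p-values and q-values of the authors' test, which covered 15762 genes.

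Adar, the gene targeted by the floxed alleles, was not lower in TMX. The authors' deposited table listed Adar (ENSMUSG00000027951.16, GRCm38 chromosome 3, 89715022 to 89753446, plus strand) at 19.5 FPKM in con and 52.0 FPKM in TMX. The log2 fold change in the authors' deposited table was 1.37, with a p-value of 0.00745 and a q-value of 0.0575, which missed the threshold of 0.05. Adjusted over protein-coding genes alone, a filter chosen after the data were seen, the authors' p-value for Adar gave an adjusted p of 0.0489, under the threshold. It gave 0.0562 over genes with a mean FPKM of at least 1 and 0.106 with no filter on low values, both above the threshold. The paralogs Adarb1 and Adarb2 were at 0.0573 and 0.0206 FPKM in con and 0.227 and 0.0121 FPKM in TMX in the authors' deposited table, and neither was tested. The direction of Adar goes against the reading of TMX as the deleted condition, and every direction below is given for the condition labelled TMX. The deleted exons are not given in the sources used here and a gene-level FPKM also counts the exons that remain, so this value checks neither the deletion nor the labels.

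The crypt transcriptome differed widely between the conditions. Of 15762 tested genes, the authors' deposited table called 1041 higher and 899 lower in TMX, which is 12.3%. The median log2 fold change of the called genes was 1.39 among those that rose and -1.37 among those that fell in the authors' deposited table. On the same scale, 859 of the genes that rose and 765 of those that fell changed at least 2-fold. Protein-coding genes made up 948 of the calls higher in TMX and 861 of those lower, out of 12516 tested. The direction varied with expression level in the authors' deposited table. Below a mean of 1 FPKM, 190 called genes rose and 36 fell, whereas at 100 FPKM or more 27 rose and 117 fell.

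The largest rises by the fixed rule were led by S100a4, a calcium-binding protein, from 1.34 to 202 FPKM with a log2 fold change of 6.44 and a q-value of 0.0141 in the authors' deposited table. Slfn4, a Schlafen family gene, rose from 6.55 to 593 FPKM and Saa3, an acute-phase serum amyloid A, from 2.66 to 263 FPKM in the authors' deposited table. Areg, which encodes the EGF receptor ligand amphiregulin, rose from 7.35 to 364 FPKM, and Lgals1, or galectin 1, from 2.52 to 133 FPKM, as the authors' deposited table lists them. Ctla2a rose from 0.996 to 84.8 FPKM and Arg1, which encodes arginase 1, from 0.287 to 53.4 FPKM in the authors' deposited table. Ly6g, a granulocyte surface marker, was listed at 0 in con and at 36.2 FPKM in TMX in the authors' deposited table. The 7 genes after S100a4 each had the lowest q-value that the authors' deposited table holds, 0.00112.

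Among the largest falls, Pla2g4c, a cytosolic phospholipase A2, went from 438 to 1.77 FPKM, a log2 fold change of -7.31 in the authors' deposited table. Gsdmc2, a gasdermin gene with close paralogs beside it, fell from 171 to 0.117 FPKM, and Dnase1 fell from 50.3 to 0.431 FPKM, both with a q-value of 0.00200 in the authors' deposited table. Digestive enzymes of the brush border followed, with Plb1 falling from 62.0 to 0.803 FPKM, Enpp7 from 139 to 3.16 FPKM and Mep1a from 123 to 3.43 FPKM in the authors' deposited table. Selenop, a secreted selenium carrier, fell from 3791 to 126 FPKM in the authors' deposited table. Rprl3, a small noncoding RNA gene, was at 135 FPKM in con and listed at 0 in TMX in the authors' deposited table. Apart from Gsdmc2 and Dnase1, these falls had the q-value 0.00112 in the authors' deposited table.

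**Figure D1:**
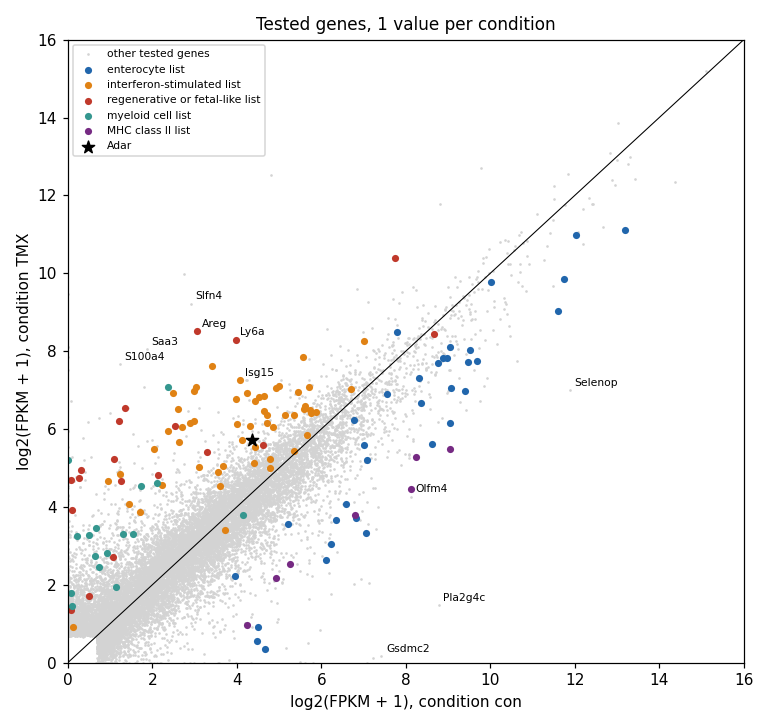
Each point is 1 of the 15762 genes tested by the authors, with log2(FPKM + 1) in con on the x axis and in TMX on the y axis; the line marks equal values, colours mark 5 gene lists and the star marks Adar. Interferon-stimulated and regenerative genes lie mostly above the line, MHC class II genes lie below it, as do all but 1 of the enterocyte genes, and Adar lies above it at 19.5 and 52.0 FPKM.

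Interferon-stimulated genes were higher in TMX as a group. Of 55 tested members, 42 rose and none fell in the authors' deposited table, and adjusted over the list alone 45 rose and none fell. By the unadjusted p-values of the authors' deposited table, 46 members were higher and none lower at a p under 0.05. Bst2, which tethers budding virions, rose from 5.51 to 65.5 FPKM, Ddx60 from 22.1 to 113 FPKM and Cmpk2 from 10.7 to 28.8 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The ubiquitin-like modifier Isg15 rose from 15.9 to 151 FPKM, the antiviral GTPase gene Mx1 from 7.13 to 134 FPKM and Rsad2, or viperin, from 5.13 to 90.9 FPKM, at the same q-value in the authors' deposited table. The interferon-stimulated list had a median log2 fold change of 1.83, above all 10000 matched random lists, whose highest median was 0.32. Myeloid cell markers moved with this list, with a median log2 fold change of 2.05, whereas T and NK cell markers had a median of -0.97.

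The list of double-stranded RNA sensors had a higher median in TMX, but its members moved both ways. Of 20 tested members, 13 had a log2 fold change above 0 and 7 below. The authors' deposited table called 7 of 20 tested members higher and 1 lower, and adjusted over the list alone 8 were higher and 2 lower. The RIG-I gene Ddx58 rose from 25.4 to 81.2 FPKM, the PKR gene Eif2ak2 from 25.2 to 70.2 FPKM and Oas1a from 16.5 to 51.3 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The MDA5 gene Ifih1 rose from 47.7 to 94.9 FPKM with a q-value of 0.0282 in the authors' deposited table. Nlrp6, an innate sensor of the intestinal epithelium, fell from 23.3 to 7.26 FPKM with a q-value of 0.00112 in the authors' deposited table. Zbp1, a sensor of Z-form nucleic acid, was at 52.9 and 84.5 FPKM with a q-value of 0.302 in the authors' deposited table. This list shares 9 genes with the interferon-stimulated list, and its median log2 fold change of 0.40 lay at the 99.8th percentile of random lists, beside the myeloid marker median of 2.05. Of the interferon-stimulated list, 54 of 55 members had a log2 fold change above 0. No median was taken over the sensors that are not shared, so a rise of those as a group is not shown.

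Interferon genes themselves gave little signal. Ifnb1 was listed at 0 in both conditions, Ifnl2 and Ifnl3 were listed at 0 in con and at 0.460 and 0.346 FPKM in TMX, and the authors' deposited table tested neither these nor Ifna4 and Ifng. Of the 9 tested members of the list of interferons and their receptors, 1 fell and none rose in the authors' deposited table, and the counts were the same when adjusted over the list alone. Before adjustment, 3 were lower and none higher at a p under 0.05 in the authors' deposited table. The member that fell was Ifngr2, a subunit of the interferon-gamma receptor, from 28.5 to 6.37 FPKM with a q-value of 0.00112 in the authors' deposited table. The median log2 fold change was -0.07, at the 41.4th percentile.

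Genes induced by interferon-gamma moved in both directions. Of 24 tested members, 7 rose and 2 fell in the authors' deposited table, and adjusted over the list alone 11 rose and 3 fell. The guanylate-binding protein gene Gbp3 rose from 1.94 to 33.7 FPKM, the immunity-related GTPase gene Iigp1 from 16.8 to 74.3 FPKM and the chemokine gene Cxcl11 from 1.44 to 17.4 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The members that fell were Ciita, the master transactivator of MHC class II, from 17.9 to 0.945 FPKM with a q-value of 0.00112, and the transcription factor Irf1, from 132 to 59.8 FPKM with a q-value of 0.0307, in the authors' deposited table. The list's median log2 fold change was 0.58, at the 99.95th percentile, and myeloid markers, with a median of 2.05, were higher as well.

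MHC class II genes fell without exception among the 7 tested in the authors' deposited table, and all 7 also fell when adjusted over the list alone. H2-Aa went from 276 to 20.9 FPKM, H2-Ab1 from 524 to 43.5 FPKM and the invariant chain gene Cd74 from 300 to 37.7 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The class II list had a median log2 fold change of -3.03, below all 10000 random lists, whose lowest median was -1.90. T and NK cell markers were lower as well, with a median of -0.97, whereas myeloid markers, with a median of 2.05, were higher. Of 19 tested MHC class I and antigen-processing genes, 2 rose and none fell in the authors' deposited table, and adjusted over the list alone 3 rose and 2 fell. At an unadjusted p under 0.05, 3 were higher and 4 lower in the authors' deposited table. H2-Q4 rose from 20.6 to 52.7 FPKM and H2-Q7 from 4.88 to 24.0 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The class I light chain B2m was at 2487 FPKM in con and 1296 FPKM in TMX with a q-value of 0.213 in the authors' deposited table, and the class I list did not stand apart, at the 6.88th percentile with a median of -0.40.

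Chemokine and cytokine genes were higher in TMX as a group, with exceptions. Of 24 tested members, 10 rose and 4 fell in the authors' deposited table, and adjusted over the list alone 11 rose and 5 fell. Ccl20, a ligand of CCR6, rose from 2.65 to 50.4 FPKM and the macrophage growth factor gene Csf1 from 0.453 to 4.69 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The monocyte attractants Ccl2 and Ccl7 were listed at 0 in con and at 3.57 and 3.94 FPKM in TMX with the same q-value in the authors' deposited table. The members that fell were Tnfsf10, or TRAIL, from 18.5 to 4.29 FPKM, the T cell attractant Ccl5 from 24.1 to 4.88 FPKM, Ccl28 from 15.1 to 5.26 FPKM and the small-intestinal chemokine Ccl25 from 523 to 182 FPKM in the authors' deposited table. The median log2 fold change of 1.80 lay above all 10000 random lists, and the myeloid marker median of 2.05 moved in the same direction, with larger values of 2.87 and 3.14 at a pseudocount of 0.1.

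Targets of NF-kB were higher in TMX as a group. The authors' deposited table called 4 of 17 tested members higher and none lower, with the same counts when adjusted over the list alone. By the unadjusted p-values of the authors' deposited table, 6 were higher and 1 lower at a p under 0.05. Tnfaip2 rose from 0.809 to 8.26 FPKM and Ier3 from 1.29 to 10.1 FPKM with a q-value of 0.00112 each, Nfkb2 from 3.30 to 8.60 FPKM and the adhesion molecule gene Icam1 from 0.908 to 3.17 FPKM, in the authors' deposited table. The list's median log2 fold change was 0.64, at the 99.9th percentile, and the myeloid marker median of 2.05 lay on the same side of 0.

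Antimicrobial and mucosal defence genes held more calls lower than higher in TMX. Of 17 tested members, 2 rose and 8 fell in the authors' deposited table, with the same counts when adjusted over the list alone. Saa1 fell from 156 to 9.85 FPKM, the C-type lectin gene Reg3a from 44.2 to 4.10 FPKM, Retnlb from 506 to 121 FPKM and Duoxa2, the maturation factor of an epithelial oxidase, from 111 to 25.9 FPKM, each with a q-value of 0.00112 in the authors' deposited table. Against the list, Saa3 rose as given above and the protease inhibitor gene Slpi rose from 1.32 to 29.8 FPKM with a q-value of 0.00112 in the authors' deposited table. Reg3b was at 21087 FPKM in con and 5243 FPKM in TMX, but with a q-value of 0.480 in the authors' deposited table. S100a8 went the other way, with a log2 fold change of 6.64 and a q-value of 0.547 in the authors' deposited table. S100a9, also not called, was at least 16-fold higher in TMX by the plain ratio of FPKM. Of the 17 tested members, 5 had a log2 fold change above 0 and 12 below. The defence list had a median log2 fold change of -1.42, below all 10000 random lists, while the mean was 0.15, so the median and the mean differ in sign.

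Genes of the integrated stress response were higher in TMX as a group. Of 23 tested members, 12 rose and none fell in the authors' deposited table, and adjusted over the list alone 13 rose and none fell. Before adjustment, 13 were higher and none lower at a p under 0.05 in the authors' deposited table. Chac1, which degrades glutathione, rose from 0.924 to 13.1 FPKM, the cystine transporter gene Slc7a11 from 1.03 to 15.8 FPKM, the transcription factor gene Atf3 from 23.5 to 88.3 FPKM and the serine synthesis gene Psat1 from 10.98 to 39.7 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The transcript of Atf4, which is regulated largely by translation, was at 82.5 and 83.2 FPKM with a q-value of 0.991 in the authors' deposited table. The median log2 fold change of 1.42 lay above all 10000 random lists. Myeloid markers, with a median of 2.05, and stromal, muscle and endothelial markers, with a median of 0.73, were higher as well. T and NK cell markers were lower, with a median of -0.97. Of 19 tested genes of the unfolded protein response of the endoplasmic reticulum, none rose or fell in the authors' deposited table, over all genes tested, adjusted over the list alone or at an unadjusted p under 0.05. The chaperone gene Hspa5, or BiP, was at 207 and 283 FPKM with a q-value of 0.550 in the authors' deposited table, and the list's median of -0.19 lay at the 31.1th percentile.

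Targets of p53 were higher in TMX as a group, with exceptions. Of 21 tested members, 5 rose and 2 fell in the authors' deposited table, and adjusted over the list alone 9 rose and 2 fell, while 11 were higher and 2 lower at an unadjusted p under 0.05. Plk2 rose from 1.76 to 15.6 FPKM with a q-value of 0.00112 and the nuclease gene Aen from 7.72 to 38.0 FPKM with a q-value of 0.00355, whereas Sesn1 fell from 29.3 to 4.72 FPKM and the death receptor gene Fas from 15.4 to 4.14 FPKM, both at 0.00112, in the authors' deposited table. The cell cycle inhibitor Cdkn1a was at 12.8 and 15.4 FPKM with a q-value of 0.766 in the authors' deposited table. The p53 list shares 2 genes with the integrated stress response list and 5 with the cell death list, and no median was taken without them. The list's median log2 fold change of 0.76 lay above all 10000 random lists. Medians on the same side of 0 were 2.05 for myeloid markers and 0.73 for stroma, muscle and endothelium, whereas that of T and NK cells was -0.97.

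Cell death genes went both ways. Of 34 tested members, 4 rose and 6 fell in the authors' deposited table, and adjusted over the list alone 5 rose and 7 fell, while 7 were higher and 10 lower at an unadjusted p under 0.05. Mlkl, the effector of necroptosis, rose from 10.8 to 43.6 FPKM with a q-value of 0.00112 and the kinase gene upstream of it, Ripk3, from 9.91 to 30.8 FPKM with a q-value of 0.00281 in the authors' deposited table. Fas, Tnfsf10 and Gsdmc2 were among the members that fell in the authors' deposited table. The cell death list's median of -0.06 lay at the 43.3th percentile. Immediate early genes had 5 of 14 tested members higher and none lower in the authors' deposited table, and 7 higher and none lower when adjusted over the list alone. At an unadjusted p under 0.05, 9 were higher and none lower in the authors' deposited table. Egr1 rose from 0.803 to 19.3 FPKM with a q-value of 0.00112 and Dusp1 from 1.63 to 14.6 FPKM with a q-value of 0.01 in the authors' deposited table, and the list's median of 0.73 lay at the 99.9th percentile. Beside it stood medians of 2.05 for myeloid markers, 0.73 for stroma, muscle and endothelium and -0.97 for T and NK cells.

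Enterocyte genes, which serve absorption and digestion at the villus, were lower in TMX as a group. Of 34 tested members, 17 fell and none rose in the authors' deposited table, and adjusted over the list alone 24 fell and none rose. By the unadjusted p-values of the authors' deposited table, 25 were lower and none higher at a p under 0.05. Adenosine deaminase (Ada) fell from 67.6 to 5.22 FPKM, the peptidase gene Ace from 74.3 to 7.25 FPKM, Apoc3 from 112 to 12.05 FPKM and the intestinal alkaline phosphatase gene Alpi from 80.5 to 11.6 FPKM, each with a q-value of 0.00112 in the authors' deposited table. Fabp1, a fatty acid-binding protein gene, was the 1 tested member with a higher value in TMX, at 222 FPKM in con and 362 FPKM in TMX with a q-value of 0.221 in the authors' deposited table. The median log2 fold change of -1.88 lay below all 10000 random lists. In con the enterocyte list had a median of 325 FPKM, and how much villus epithelium the preparations carried is unknown. Markers of other cell types moved too, with medians of 2.05 for myeloid cells, 0.73 for stroma, muscle and endothelium and -0.97 for T and NK cells. A change in the mix of cells was not tested for this list.

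Genes of oxidative phosphorylation were lower as a group, with 14 of 29 tested members falling and none rising in the authors' deposited table. Adjusted over the list alone 22 fell and none rose, and at an unadjusted p under 0.05, 23 fell and none rose, from the p-values of the authors' deposited table. Cox8a fell from 202 to 69.6 FPKM, Sdhb from 114 to 44.5 FPKM and Ndufa1 from 211 to 85.7 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The list's median log2 fold change of -0.97 lay below all 10000 random lists. For tested genes with a mean of 100 FPKM or more, the median log2 ratio of TMX over con was -0.23. Enterocyte genes and T and NK cell markers were lower too, with medians of -1.88 and -0.97. Markers of myeloid cells and of stroma, muscle and endothelium were higher, at 2.05 and 0.73. Whether the mix of cells carries the fall was not tested.

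Secretory lineages did not move alike. Enteroendocrine genes were higher as a group, with 7 of 16 tested members higher and none lower in the authors' deposited table, and 8 higher and none lower when adjusted over the list alone. Before adjustment, 10 were higher and none lower at a p under 0.05 in the authors' deposited table. Tph1, which makes serotonin, rose from 3.30 to 25.9 FPKM and the incretin gene Gip from 20.6 to 70.5 FPKM, each with a q-value of 0.00112, and Pyy rose from 10.6 to 33.1 FPKM and Nts from 88.0 to 219 FPKM in the authors' deposited table. The median of 0.88 lay above all 10000 random lists. Of 15 tested goblet cell genes, 4 fell and none rose in the authors' deposited table, and 5 fell and none rose both when adjusted over the list alone and at an unadjusted p under 0.05. Klk1 fell from 60.02 to 11.8 FPKM, the trefoil factor gene Tff3 from 1284 to 537 FPKM, Capn9 from 5.47 to 1.23 FPKM and Clca1 from 777 to 183 FPKM in the authors' deposited table, the last with a q-value of 0.0491. The mucin gene Muc2 was at 262 and 252 FPKM with a q-value of 0.975 in the authors' deposited table, and the goblet list, with a median of -0.54, did not stand apart at the 2.74th percentile, but did at the 2.10th with no filter on low values.

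Of 17 tested Paneth cell genes, 1 rose and 2 fell in the authors' deposited table, with the same counts when adjusted over the list alone. The lectin gene Itln1 fell from 1396 to 400.3 FPKM and Ang4 from 2878 to 815 FPKM, with q-values of 0.01 and 0.0360, whereas the stress-response gene Nupr1 rose from 43.2 to 119 FPKM with a q-value of 0.00355 in the authors' deposited table. Lysozyme (Lyz1) was at 4656 and 3235 FPKM with a q-value of 0.903 in the authors' deposited table, and the list's median of -0.47 lay at the 9.96th percentile. Of 10 tested tuft cell genes, 2 fell and none rose in the authors' deposited table, and adjusted over the list alone 2 fell and 1 rose. At an unadjusted p under 0.05, 4 tuft cell genes were lower and 2 higher in the authors' deposited table. Rgs13 fell from 28.4 to 8.15 FPKM with a q-value of 0.00112 and Siglecf from 1.60 to 0.338 FPKM with a q-value of 0.00676 in the authors' deposited table. The tuft list's median of -0.51 lay at the 0.56th percentile, but at the 3.85th when genes below a mean of 1 FPKM were left out.

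Stem cell genes did not stand apart as a group. Of 18 tested members, 1 rose and 2 fell in the authors' deposited table, with the same counts when adjusted over the list alone, while 2 were higher and 7 lower at an unadjusted p under 0.05. Olfm4, an abundant crypt base marker, fell from 277 to 18.2 FPKM with a q-value of 0.00112 and Slc12a2 from 54.2 to 25.4 FPKM with a q-value of 0.0176, whereas Igfbp4 rose from 5.15 to 21.2 FPKM with a q-value of 0.0374 in the authors' deposited table. The stem cell receptor gene Lgr5 was at 4.68 and 2.64 FPKM with a q-value of 0.189 in the authors' deposited table, and the list's median of -0.24 lay at the 8.40th percentile. Of 37 tested cell cycle genes, 4 rose and none fell in the authors' deposited table, with the same counts when adjusted over the list alone. By the unadjusted p-values of the authors' deposited table, 6 were higher and none lower at a p under 0.05. Myc rose from 7.51 to 35.3 FPKM, the ribonucleotide reductase gene Rrm2 from 10.6 to 33.0 FPKM, Mcm3 from 3.41 to 9.15 FPKM and Ccnd2 from 15.98 to 35.3 FPKM in the authors' deposited table. The proliferation marker Mki67 was at 34.6 and 49.5 FPKM with a q-value of 0.411 in the authors' deposited table, and the list's median of 0.25 lay at the 98.3th percentile.

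Genes of the regenerative or fetal-like state, which epithelium enters after injury, had the highest median of the 28 lists. Of 19 tested members, 13 rose and none fell in the authors' deposited table, with the same counts when adjusted over the list alone and at an unadjusted p under 0.05. Annexin genes Anxa1 and Anxa3 rose from 1.30 to 72.7 FPKM and from 4.83 to 66.5 FPKM, each with a q-value of 0.00112 in the authors' deposited table. The hyaluronan receptor gene Cd44 rose from 8.89 to 41.4 FPKM and Ly6a, or Sca-1, from 14.8 to 314 FPKM at the same q-value in the authors' deposited table. The regenerative list's median of 3.53 lay above all 10000 random lists, whose highest median was 0.83. Some members, such as Anxa1 and Cd44, are also expressed by leukocytes and stroma, whose markers had medians of 2.05 for myeloid cells and 0.73 for stroma, muscle and endothelium, or 2.09 and 2.11 among genes with a mean FPKM of at least 1.

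Markers of other cell types that a crypt preparation can carry moved in different directions. Of 16 tested myeloid markers, 11 rose and none fell in the authors' deposited table, with the same counts when adjusted over the list alone. Before adjustment, 12 were higher and none lower at a p under 0.05 in the authors' deposited table. Beside Ly6g, the macrophage and granulocyte lysozyme Lyz2 rose from 4.20 to 135 FPKM, Fcer1g from 3.33 to 23.7 FPKM, Cd14 from 1.47 to 8.96 FPKM and Itgam from 1.94 to 8.85 FPKM, each with a q-value of 0.00112 in the authors' deposited table. Their median of 2.05 lay above all 10000 random lists. The pan-leukocyte gene Ptprc was at 16.6 and 12.9 FPKM with a q-value of 0.649 in the authors' deposited table. Of 18 tested T and NK cell markers, 5 fell and none rose in the authors' deposited table, and 7 fell and none rose both when adjusted over the list alone and at an unadjusted p under 0.05. The granzyme genes Gzma and Gzmb fell from 270 to 40.4 FPKM and from 33.2 to 3.40 FPKM, Cd7 from 7.78 to 1.71 FPKM and the T cell receptor component Cd3g from 8.77 to 2.29 FPKM in the authors' deposited table. The median of -0.97, or -1.50 at a pseudocount of 0.1, lay below all 10000 random lists.

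Stromal, muscle and endothelial markers included 8 that rose and 1 that fell among 16 tested in the authors' deposited table, and 11 that rose and 1 that fell when adjusted over the list alone, while 12 were higher and 1 lower at an unadjusted p under 0.05. The collagen genes Col3a1 and Col1a2 rose from 2.97 to 52.0 FPKM and from 0.738 to 13.5 FPKM and the intermediate filament gene Vim from 4.58 to 36.1 FPKM, each with a q-value of 0.00112 in the authors' deposited table. Kit, a receptor gene of mast and pacemaker cells, fell from 9.17 to 1.88 FPKM with a q-value of 0.00112, and the smooth muscle gene Acta2 was at 0.775 and 0.753 FPKM with a q-value of 0.989, in the authors' deposited table. The median of 0.73 lay at the 99.85th percentile, and it depends on the processing, at 2.08 with a pseudocount of 0.1 and 2.11 among genes with a mean FPKM of at least 1. Of 9 tested B and plasma cell markers, 1 rose and none fell in the authors' deposited table, with the same counts when adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher and none lower in the authors' deposited table. The gene that rose was the immunoglobulin light chain Igkc, from 90.8 to 167 FPKM with a q-value of 0.0401 in the authors' deposited table, and the list's median of 0.14 lay at the 54.1th percentile, but among protein-coding genes alone it was -0.37, at the 2.70th. Of 3 tested erythroid markers, none rose or fell in the authors' deposited table, over all genes tested, adjusted over the list alone or at an unadjusted p under 0.05, and their median of 0.43 lay at the 66.2th percentile.

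**Figure D2:**
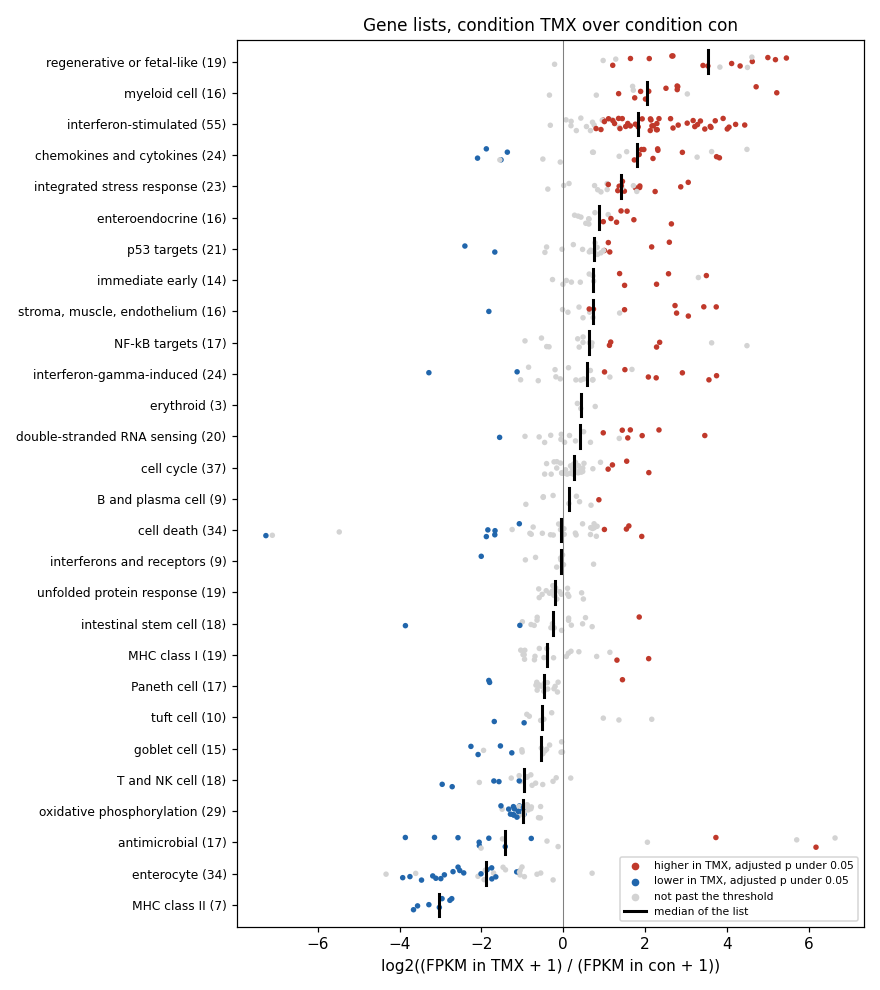
Each point is a tested member of 1 of 28 gene lists, placed by log2((FPKM in TMX + 1) / (FPKM in con + 1)); red and blue mark genes called higher and lower in TMX by the authors, the bar is the list's median and the number of tested members stands in parentheses. The medians run from -3.03 for MHC class II to 3.53 for regenerative or fetal-like genes, and 13 lists stand apart as higher and 6 as lower.

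Each comparison rests on 1 pooled value per condition and on the authors' test, and at a stricter q-value threshold of 0.01 the authors' deposited table holds 614 genes higher and 544 lower in TMX. When the p-values of the authors' deposited table were adjusted over all 29029 genes listed above 0, the calls of Ang4, Ccl25, Clca1, Ifih1, Igfbp4, Igkc and Irf1 ended, with adjusted p-values from 0.0519 to 0.0904. The genes added to the 15762 were not tested by the authors, so this step could only end calls.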

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

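In this part, the filter on mean FPKM, protein-coding genes alone and centring on genes of at least 20 FPKM were chosen only after the data were seen. All 8 alternatives reuse the authors' p-values, so pseudocount, rescaling and centring can change directions and sizes but not p-values. At an adjusted p under 0.01 the counts moved from 1041 to 614 genes higher and from 899 to 544 lower in TMX, by construction of the threshold. The other alternatives gave 853 to 1041 genes higher and 746 to 915 lower. With no filter on low values 860 rose and 746 fell, and all 1606 were among the 1940 calls of the report. The genes added there were not tested by the authors. That alternative therefore only adjusts the same p-values over more genes, and for the calls it could only remove some. Adar kept its direction, with log2 fold changes of 1.31 to 1.49. Its adjusted p was 0.0489, with a log2 fold change of 1.37, among protein-coding genes alone, where fewer genes are tested, and 0.0562 to 0.106 under the other gene filters.

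For the 174 named genes, with Adar left out of the counts that follow, 1022 of the values under an alternative kept their direction and side of the threshold, 7 lost their call and 3 changed sign. The 7 were Ifih1, Irf1, Ang4, Igfbp4, Ccl25, Igkc and Clca1 without a filter on low values, where more genes are adjusted for. The sign changed for Atf4 after rescaling (-0.051), and for Acta2 (0.034) and Muc2 (0.064) after centring, all far from the threshold. Between 18 and 20 gene lists stood apart under the alternatives, against 19. Rescaling and centring shift a list and its random lists almost alike, so these settings could hardly change which lists stood apart. The goblet list stood apart without a filter, at the 2.10th percentile, and the tuft list did not at a mean FPKM of at least 1, at the 3.85th. Medians changed sign for B and plasma cells among protein-coding genes alone (-0.37), and for interferons and receptors (0.043) and cell death (0.046) after centring, and none of these lists stood apart. With a pseudocount of 0.1 the largest shifts of list medians relative to their size were to 2.08 for stroma, muscle and endothelium (from 0.73), 2.87 for chemokines and cytokines (from 1.80), 3.14 for myeloid cells (from 2.05), -1.50 for T and NK cells (from -0.97) and 0.65 for erythroid cells (from 0.43). The median log2 ratio of TMX over con was 0.06 over all tested genes and -0.12 over those with a mean of at least 20 FPKM, a shift that the centring removes.

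No paired analysis was possible because the table holds 1 pooled value per condition. For the same reason the count-based test, leaving out each library, other splits of the libraries, the gene set tests with a preset or estimated correlation and the overlap with a new fit were planned but not run. Depth is unknown, so what it limits cannot be stated.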

Other observations

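The gene families in this part, the tests on Adar and on myeloid and stromal markers and the comparison of gains between pseudogenes and receptor genes were chosen only after the values were seen, while the other tests on receptor genes and low-FPKM calls were written down before their results. Some gene families held calls higher and none lower in TMX. Of 8 tested protein-coding Ly6 and Gml genes, which lie on chromosome 15 from 74762056 to 75159126 (GRCm38), 6 rose and none fell in the authors' deposited table, also when adjusted over the family alone and at an unadjusted p under 0.05. Ly6d rose from 1.55 to 91.8 FPKM and Gml2 from 2.15 to 46.7 FPKM, each with a q-value of 0.00112 in the authors' deposited table. All 6 tested Schlafen genes rose, among them Slfn5 from 1.74 to 15.9 FPKM and Slfn9 from 4.59 to 16.6 FPKM in the authors' deposited table. Of 10 tested genes of the HIN-200 family, which includes DNA sensors, 6 rose and none fell, including Ifi204 from 0.306 to 35.8 FPKM and Aim2 from 19.4 to 61.0 FPKM, and 7 were higher and none lower at an unadjusted p under 0.05 in the authors' deposited table. Of 12 tested S100a genes, 4 rose and none fell in the authors' deposited table, with the same counts at an unadjusted p under 0.05, among them S100a6 from 213 to 1343 FPKM. Dual specificity phosphatase genes, which restrain MAP kinases, had 7 of 16 tested members higher and none lower, and 8 higher and none lower at an unadjusted p under 0.05, in the authors' deposited table. Some of these genes are also expressed by myeloid cells, whose markers had a median log2 fold change of 2.05.

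Detoxification and transport families held more calls lower than higher in TMX. Of 23 tested cytochrome P450 genes of families Cyp2, Cyp3 and Cyp4, 9 fell and none rose, with 15 lower and 1 higher at an unadjusted p under 0.05, in the authors' deposited table. Cyp4v3 fell from 71.8 to 3.95 FPKM and Cyp2c68 from 13.9 to 0.759 FPKM in the authors' deposited table. Of 11 tested Ugt genes, which conjugate glucuronic acid, 4 fell and none rose, also at an unadjusted p under 0.05, among them Ugt2b34 from 202 to 51.9 FPKM in the authors' deposited table. Of 252 tested solute carrier genes, 16 rose, 60 fell and 176 were not called, the fallen including the amino acid transporter gene Slc6a19 from 219.9 to 41.7 FPKM, in the authors' deposited table. The mucosal mast cell protease genes Mcpt1 and Mcpt2 fell from 32.9 to 3.13 FPKM and from 32.4 to 3.23 FPKM, each with a q-value of 0.00112 in the authors' deposited table. Neither the 89 tested ribosomal protein genes nor the 38 tested proteasome subunit genes held a call in the authors' deposited table. Their median log2 fold changes of 0.05 and 0.23 still lay at the 98.6th and 99.5th percentiles of matched random lists. A set without any call can therefore stand apart by the rule used here. At an unadjusted p under 0.05, 1 ribosomal protein gene was higher and 1 lower, and 2 proteasome genes were higher and 1 lower, in the authors' deposited table. Beside Gsdmc2, its neighbours Gsdmc3 and Gsdmc4 (chromosome 15, 63824346 to 63912297 for all 3) were at 44.2 and 149 FPKM in con and 0.0174 and 0.0852 FPKM in TMX, with q-values of 0.564 and 0.0743, in the authors' deposited table. Of 87 tested protein-coding genes that differed at least 16-fold by the plain ratio of FPKM, with nothing added to values near 0, and reached 10 FPKM in the higher condition, 18 were not called, among them S100a8 (0.0559 and 104 FPKM), Cxcl1 (0.320 and 28.6 FPKM) and Cxcl2 (0.0164 and 11.5 FPKM), in the authors' deposited table.

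Adar was higher in the condition read as its deletion. The gene has an interferon-inducible promoter, and its log2 fold change lay at the 38.2th percentile of the 55 interferon-stimulated genes, with 21 of them below it. This is consistent with the hypothesis that the gene-level signal follows the interferon-stimulated genes while a deleted segment is masked. That the condition names were exchanged cannot be told apart from this by the log2 fold change of 1.37, because no value for the deleted exons was used here.

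Myeloid and stromal markers were higher in TMX while T and NK cell markers were lower. A lower epithelial share alone would raise the markers of other cell types, except of cells that are lost together with the epithelium. The T and NK median log2 fold change of -0.97 lay below all 10000 random lists. It does not decide this, since lymphocytes that lie within the epithelium would fall with it. More myeloid cells in the TMX preparations may account for 15 of 16 tested myeloid markers having a higher value. The 1 myeloid list member with a lower value was the pan-leukocyte gene Ptprc, at a log2 fold change of -0.34 and a q-value of 0.649 in the authors' deposited table. Ptprc does not decide whether there were more myeloid cells, since T cells also express it. The genotype, or a change in expression within cells already present, stays open and was not tested.

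Genes that crypts are not known for had more signal in TMX. Of 2012 genes named as olfactory, vomeronasal or taste receptors, 145 were above 0 in con and 665 in TMX in the authors' deposited table. These receptor genes were picked by name with no filter on gene type, so receptor pseudogenes could enter. The gene models Gm10800 and Gm10801 lie on chromosome 2, at 98666547 to 98667301 and 98662237 to 98664083. They were at 27.1 and 5.71 FPKM in con and 5860 and 1011 FPKM in TMX in the authors' deposited table. Their q-values in the authors' deposited table were 0.352 and 0.00112. The mean FPKM of all receptor genes was 2.79 times as high in TMX, with a 95% bootstrap interval over genes of 1.93 to 5.50, and 9.16 times without the 20 highest. The lower end of the interval of the second ratio, 6.95, like that of the first, argues against greater depth alone, which would leave mean FPKM in place. Whether genomic DNA in the TMX libraries is the source stays open, and no biological explanation was tested. The ratio for untested unprocessed pseudogenes was 1.81 without the 20 highest, with an interval of 1.26 to 2.64, but 0.482 with none left out. Without the 20 highest they gained a mean of 0.00304 FPKM and untested receptor genes 0.0141 FPKM, whereas DNA would add a similar signal per length. With tested genes kept in both sets the mean gains were 0.00401 FPKM and 0.0147 FPKM, and the pseudogene ratio was 1.09. Receptor pseudogenes were removed from neither set, so the receptor and pseudogene sets can share genes and are not distinct classes. For the 190 genes called higher below a mean of 1 FPKM, genomic DNA cannot be told apart from other sources. Their median gain of 1.09 FPKM was 65.8 times the mean gain of the receptor genes, but every gene called higher gained at least 0.473 FPKM, so the calls themselves fix this outcome.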
